A study of Caenorhabditis elegans with 12 samples.

How the data were processed

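Whole L4 larvae of Caenorhabditis elegans had been profiled on 12 one-colour expression arrays, in 4 groups of 3. The groups were the wild-type strain N2 and a strain lacking both metallothionein genes (MT KO), each raised at 20 °C without Cd or with 30 µM Cd. Per the labels, 200 ng of total RNA from each sample was amplified and labelled with biotin. The labels number the arrays 1 to 3 within each group but do not say whether these came from separate cultures, so every p-value measures the spread between these arrays, which may be technical.

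The deposited values are on the log2 scale, with 1 value per probe set and array. The submitters' processing notes name GCRMA, which corrects background with the probe sequence, equalises the distributions of the arrays and summarises the probes of a set; its version is not given in the sources used here. The scale was settled from the values, which run from 1.56 to 14.5 with array medians between 3.977 and 4.067. Values were used as deposited, with no further normalization, filter or floor. No detection calls or scanner intensities were used, so a low value may be background; the median of all values, 4.026, served as a reference level. For arrays, the number of replicates limits the precision.

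Of 22625 features, 77 manufacturer's control probe sets were set aside and 22548 were tested. Exactly 1 gene symbol was attached to 20766 probe sets, 887 carried several and 895 none. Symbols came from the deposited platform annotation, and 20701 of the probe sets with 1 symbol matched a gene of the RefSeq table of assembly WBcel235, which was used only for names, for the chromosome and for which genes neighbour each other; the deposited files name no genome build, so no coordinates are given. The probe sets with 1 symbol stood for 17118 genes, of which 2981 had several probe sets. No gene is named from a probe set with several symbols; numr-1, one of the genes to be named in any case, was present only on such a probe set, so no value is given for it.

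Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, 1 mean per group with 8 residual degrees of freedom, and the variances were moderated across probe sets (prior degrees of freedom 1.38, no intensity trend). Tests were made of 5 differences: Cd minus no Cd in wild type and in MT KO, MT KO minus wild type without Cd and with Cd, and the difference of the Cd responses, MT KO minus wild type, which is the interaction of strain and Cd. P-values were adjusted by the Benjamini-Hochberg method over the 22548 probe sets, and an adjusted p under 0.05 counted as a change. All tests were two-sided. A value given as ± is a group mean with its SD over 3 arrays, and the SE of a difference is that of the limma fit. In both strains the responses were compared by overlap and by correlation across probe sets, which are not independent replicates.

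The design, the genes to be named, the gene lists and most alternatives were fixed before the data were examined. In each comparison the genes named were the 10 with the largest rise and the 10 with the largest fall among changed probe sets with 1 symbol whose 3 arrays in one group all lay above the 3 of the other (for the interaction, without that condition) and whose higher group mean exceeded the median of all values. The genes mtl-1, mtl-2, cdr-1, pcs-1, hmt-1 and numr-1 were to be named in any case, and up to 4 members of each list with the smallest adjusted p could serve as examples. Any other gene named was chosen after its values were seen, and the text says so.

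The 30 gene lists were metallothioneins; cadmium-responsive cdr and numr genes; phytochelatin synthesis and metal efflux; zinc, iron and heme handling; glutathione S-transferases; antioxidant and thiol redox enzymes; cytochrome P450s. Further lists held UDP-glucuronosyltransferases, ABC transporters, cytosolic heat shock proteins, ER stress genes, mitochondrial stress genes, proteasome subunits, C-type lectins, and lysozymes and antimicrobial peptides. Markers of tissues and stage were lists of vitellogenins, oocyte and embryo markers, sperm markers, germline mitosis and meiosis markers, cuticle collagens, moulting genes, neuron markers, body wall muscle markers, pharynx markers and intestine markers. The metabolic lists were glycolysis and TCA cycle, fatty acid activation and beta-oxidation, fatty acid desaturases and elongases, methionine cycle and transsulfuration, and ribosomal proteins. For each gene the probe set with the highest mean over the 12 arrays stood for it. Each list with at least 3 measured members was tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 29 lists tested in a comparison. The test was repeated with an estimated correlation, and fry (limma), which does not compare the members with other genes, was run beside it. Members past the threshold were also counted after adjustment over the list alone.

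Alternatives to the main settings were an intensity trend or robust moderation of the variances, quantile normalization, centring of each array on its median, only the brighter probe sets, a floor under low values, a fit of only the groups compared, the replicate number as a block, array weights, a 2-fold minimum and each array left out in turn. For the lists, the mean of a gene's probe sets was a further alternative. A covariate was added after the data had been seen: the signal of the 3′ minus that of the 5′ control probe sets of GAPDH and actin, a sign of RNA integrity. The replicate number was checked as a pairing by the correlation of residuals. Other splits of the arrays were counted: all 10 for a comparison of 3 with 3 arrays and 100, drawn with a fixed seed, for the interaction. The 100 were also counted with the additive effects of strain and Cd removed from the values first, a test chosen after the data had been seen.

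The limma fit was tested on simulated data with 200 changed probe sets among 22548, made from the mean and spread of each probe set for the comparison of Cd with no Cd in wild type. Of 100 probe sets changed by 1 on the log2 scale, 89.0% were recovered with the right sign, and of 100 changed by 2, 99.0% were. Of the 201 probe sets called, 13 had not been changed. The simulated errors were normal, independent between probe sets and of equal spread on all arrays. Far more probe sets changed in the real data, and their arrays differed in spread. These rates therefore test the working of the fit and do not give its error rates on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.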

Results

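Transcript levels were measured on 12 arrays of whole C. elegans L4 larvae. Wild-type N2 animals and MT KO animals, which lack both metallothionein genes, had been raised without Cd or with 30 µM Cd, with 3 arrays per group. The study asks which transcripts respond to Cd, a toxic metal bound by metallothioneins, and how this response depends on those proteins. Values are log2 GCRMA values, and 22548 probe sets were compared with limma. Within groups, the arrays correlated at r between 0.9911 and 0.9969. The first principal component held 58.0% of the variance between arrays and the second 14.3%.

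The metallothionein genes themselves separated the strains. The 3 probe sets of mtl-2 read 11.52 ± 0.18, 11.52 ± 0.37 and 9.86 ± 0.38 (SD, n = 3) in wild type without Cd, and 3.71 ± 0.08, 3.93 ± 0.41 and 5.05 ± 0.67 in MT KO without Cd. The probe set of mtl-1 read 4.75 ± 0.32 in wild type without Cd and 9.85 ± 0.38 with Cd, against 3.57 ± 0.15 and 4.02 ± 0.22 in MT KO. The MT KO group means of mtl-1 and of 2 of the mtl-2 probe sets lay below the median of all values, 4.03, as did the mean of cdr-1 in wild type without Cd (3.73), so folds against them depend on the array's background. Among the 20 genes with the largest differences, the lower group mean lay below that median for 8 with Cd in wild type, for 7 with Cd in MT KO, and for 8 between the strains both without and with Cd.

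A sign of RNA quality differed between the groups. The signal of the 3′ minus the 5′ control probe sets of GAPDH and actin, which grows as RNA is degraded, was 1.98 ± 0.78 (log2, SD, n = 3) in wild type without Cd, 1.13 ± 0.10 in wild type with Cd, 1.38 ± 0.10 in MT KO without Cd and 0.92 ± 0.17 in MT KO with Cd. These are means of both controls, which differed. GAPDH alone gave 2.03, 0.83, 1.22 and 0.54 in the same order. Actin alone was 2.73 and 1.74 in wild type without Cd replicates 1 and 2, and between 1.25 and 1.6 in all other arrays. The mean of both may thus in part follow GAPDH and not RNA quality. This mean signal was 2.81 in wild type without Cd replicate 1, and that array also had the lowest limma array weight, 0.289. With this signal as a covariate, an alternative added after the data had been seen, 1406 of the 2693 changes with Cd in wild type were called again in the same direction, as were 4206 of 5067 in MT KO. The same held for 191 of the 371 strain differences without Cd, 1704 of 1930 with Cd and 1081 of the 1229 differences of response. Across all probe sets, the log2 differences with and without the covariate correlated at r = 0.908, 0.986, 0.883, 0.993 and 0.985, in that order.

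**Figure D1:**
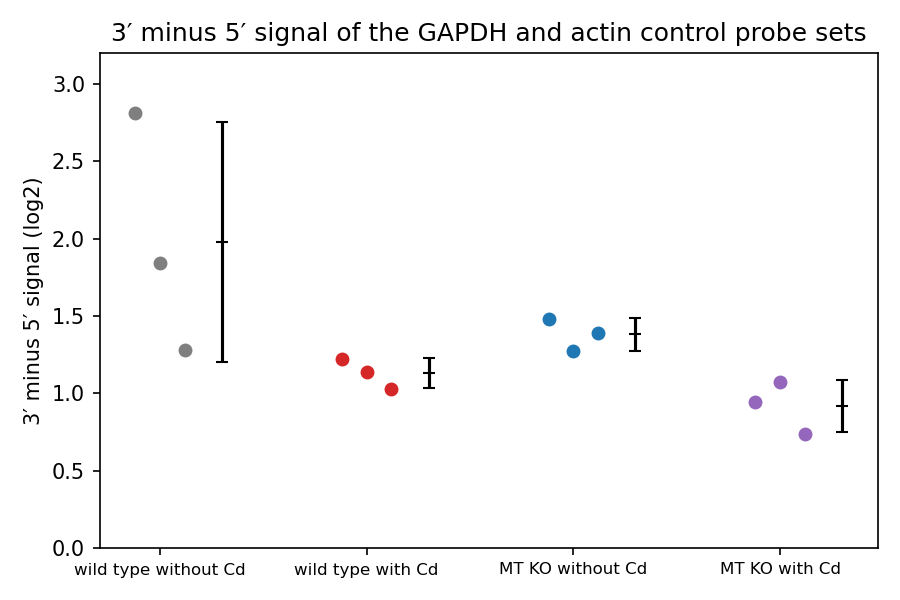
Signal of the 3′ minus the 5′ control probe sets, averaged over GAPDH and actin (log2), in each array, with the mean and SD (n = 3) of each group. Wild type without Cd had the widest spread, with a mean of 1.98.

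**Figure D2:**
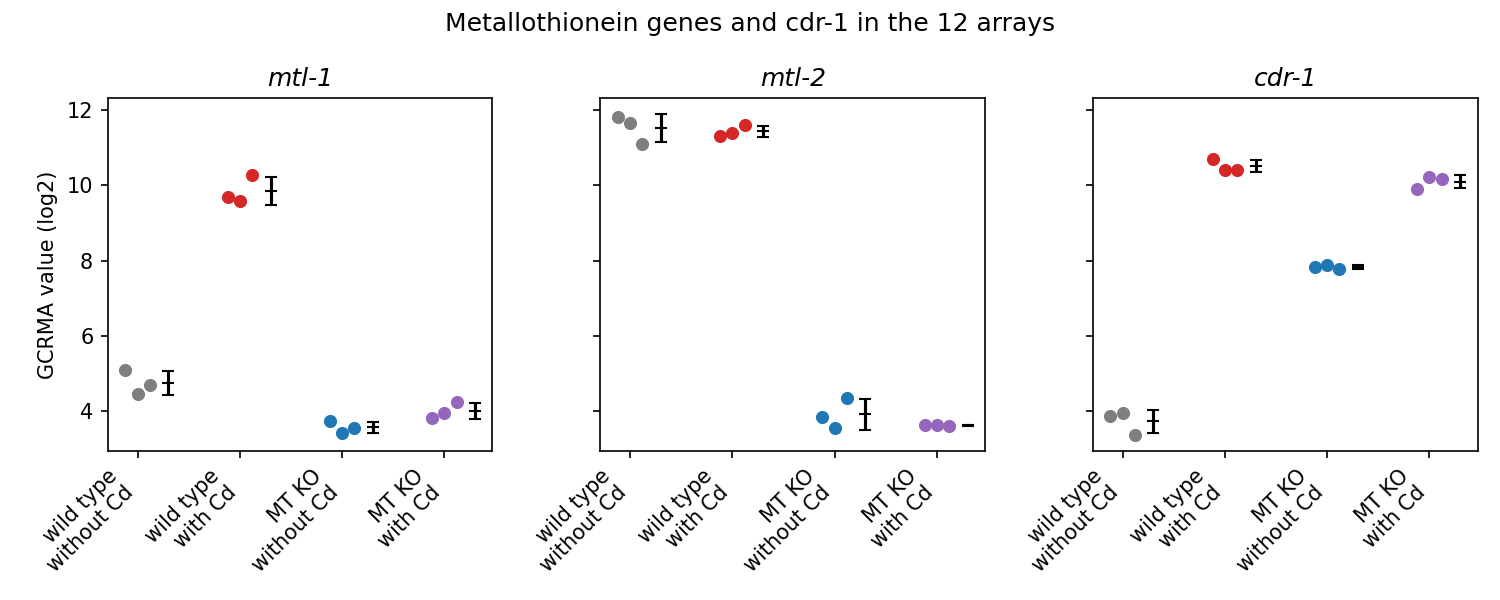
GCRMA values (log2) of mtl-1, mtl-2 (its brightest probe set) and cdr-1, with arrays as points and the mean with its SD (n = 3) beside them. With Cd, mtl-1 reached 9.85 in wild type, and cdr-1 was at 7.83 in MT KO without Cd.

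In wild type, Cd raised the metallothionein gene mtl-1 34.3-fold (log2 difference 5.1, SE 0.21, n = 3 per group, limma adjusted p = 9.76e-07). The other metallothionein gene, mtl-2, which was already among the bright signals without Cd, changed by −0.18, −0.09 and −0.42 at its 3 probe sets, with adjusted p of 0.600, 0.980 and 0.606 (limma). The largest rise was that of cdr-1, a cadmium-responsive gene related to glutathione S-transferases, from 3.73 ± 0.31 to 10.51 ± 0.16 (SD, n = 3), or 110-fold against a value in the range of background. It was followed by R08F11.4 (log2 difference 6.46, SE 0.15), F56C3.9 (5.32, SE 0.23), Y39G8B.7 (5.26, SE 0.25), F15B9.6 (4.86, SE 0.17), T08G5.1 (4.79, SE 0.22) and F44E7.5 (4.64, SE 0.18). The C-type lectin gene clec-60 rose by 4.33 (SE 0.16) and ftn-1, which encodes a ferritin that stores iron, by 4.18 (SE 0.20). The 10 largest rises had limma adjusted p between 3.65e-08 and 1.98e-06.

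The largest fall was that of nep-22, a gene of the neprilysin family of metallopeptidases, which fell by 4.65 (SE 0.11, n = 3 per group). Transcripts of argk-1, an arginine kinase gene, fell by 4.48 (SE 0.23), those of vit-6, a yolk protein gene, by 3.88 (SE 0.21) and those of cth-1, a cystathionine gamma-lyase gene, by 3.52 (SE 0.13). The others were F21C10.9 (−3.61), Y48E1B.8 (−3.51), C45B2.2 (−3.44), the C-type lectin gene clec-47 (−3.06), ZK105.1 (−2.97) and Y71G12B.18 (−2.93). Their limma adjusted p lay between 3.65e-08 and 0.00142. The phytochelatin synthase gene pcs-1 rose by 0.55 (SE 0.13, limma adjusted p = 0.025), and hmt-1, a transporter gene needed for tolerance of heavy metals, fell by 0.73 (SE 0.13, limma adjusted p = 0.00526). The call of pcs-1 was lost without any of 4 arrays: the limma adjusted p was 0.0762 and 0.0832 without wild type without Cd replicates 1 and 2, and 0.0656 and 0.0893 without wild type with Cd replicates 2 and 3. It was also lost with the 3′ minus 5′ covariate (limma adjusted p = 0.265), and that of hmt-1 in a fit of only these 6 arrays (0.0596).

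Among genes of metal handling, 3 of 6 cdr and numr genes rose and 3 did not pass; beside cdr-1, cdr-4 rose by 1.2 and cdr-2 by 0.67. The list as a whole was higher by camera (adjusted p = 0.031), but not with an estimated correlation (adjusted p = 0.138 with an estimated correlation) nor without MT KO with Cd replicate 3 (adjusted p = 0.0676) nor with the replicate number as a block (adjusted p = 0.0556). With the 3′ minus 5′ covariate the calls of cdr-2 and pgp-3 were lost (limma adjusted p = 0.081 and 0.0634). Of 7 genes of phytochelatin synthesis and metal efflux, 1 rose and 4 fell, among them pgp-3 (−0.65). Of 36 genes of zinc, iron and heme handling, 5 rose, with ftn-1 and the zinc transporter gene zipt-7.1 (1.80) foremost, and 9 fell, such as the heme-responsive genes hrg-7 (−1.85) and hrg-1 (−1.28). Of 45 glutathione S-transferase genes, 13 rose and 8 fell; gst-38 rose by 3.0, gst-24 by 2.27 and gst-33 by 1.42, while gst-13 fell by 1.11. Of 26 antioxidant and thiol redox genes, 4 fell and none rose; msra-1, a methionine sulfoxide reductase gene, fell by 2.35 and the superoxide dismutase gene sod-1 by 1.29. Camera did not call these last 4 lists.

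Of 64 UDP-glucuronosyltransferase genes, 21 fell and 5 rose, with ugt-17 (−2.64), ugt-31 (−2.17) and ugt-47 (−1.61) among those that fell. Adjusted over the list alone, 23 fell and 6 rose, and camera called the list lower (adjusted p = 7.46e-05; adjusted p = 0.0859 with an estimated correlation). Of 73 cytochrome P450 genes, 12 rose and 7 fell, such as cyp-33C7 (1.46) and cyp-13A2 (−1.66). Of 46 ABC transporter genes, 4 rose and 11 fell; pgp-8 rose by 2.95 and haf-9 fell by 0.82. Of 18 cytosolic heat shock protein genes 2 rose and 1 fell, with sip-1 at 2.56 and hsp-12.3 at −1.11. The call of hsp-12.3 was lost with the 3′ minus 5′ covariate and in a fit of only these 6 arrays (limma adjusted p = 0.0637 and 0.0597). Of 17 ER stress genes 3 fell, of 10 mitochondrial stress genes 1 rose and 3 fell, and of 220 C-type lectin genes 22 rose and 12 fell. Of 62 lysozyme and antimicrobial peptide genes 14 rose and 8 fell, with ilys-2 at 2.53, lys-7 at 1.68 and irg-8 at −2.35. Camera called none of these 7 lists, from the cytochrome P450s to the lysozymes. Of 33 proteasome subunit genes 4 fell and none rose, and camera called that list lower (adjusted p = 0.00633; adjusted p = 0.129 with an estimated correlation).

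Of 56 genes of fatty acid activation and beta-oxidation, 18 fell and 5 rose, with acox-1.1 at −1.39, acdh-1 at −1.84 and acox-1.2 at −2.15; adjusted over the list alone 21 fell and 6 rose (camera adjusted p = 3.89e-05; adjusted p = 0.0859 with an estimated correlation). Of 16 genes of the methionine cycle and transsulfuration, 6 fell and 1 rose; beside cth-1, mtrr-1 fell by 2.21 and the methionine synthase gene metr-1 by 1.58 (camera adjusted p = 0.00442; adjusted p = 0.129 with an estimated correlation). Of 18 fatty acid desaturase and elongase genes 5 fell, led by the stearoyl-CoA desaturase gene fat-7 (−2.56), and of 41 genes of glycolysis and the TCA cycle 8 rose and 2 fell, with the glyoxylate cycle gene icl-1 at 1.27; neither list was called. None of 72 ribosomal protein genes changed.

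Markers of tissues and stage also moved. Of 5 vitellogenin genes 3 fell, among them vit-1 (−2.57) and vit-2 (−1.57; camera adjusted p = 0.000561; adjusted p = 0.122 with an estimated correlation). Of 17 oocyte and embryo markers 7 rose and 1 fell, with cpg-1 at 1.0 and egg-1 at 0.60 (camera adjusted p = 0.00074; adjusted p = 0.129 with an estimated correlation), and of 10 pharynx markers 6 rose, with tnt-4 at 0.75 and pha-4 at 0.50 (camera adjusted p = 3.89e-05; adjusted p = 0.129 with an estimated correlation). With the 3′ minus 5′ covariate the calls of cpg-1 and pha-4 were lost (limma adjusted p = 0.0576 and 0.0889), as were those of the pharynx markers marg-1 and myo-5 (0.123 and 0.0836). The call of myo-5 also depended on single arrays: the limma adjusted p was 0.0685 and 0.0555 without wild type without Cd replicates 2 and 3, and 0.0726 and 0.0748 without wild type with Cd replicates 2 and 3. Of 72 sperm markers 2 fell by the test over all probe sets and none adjusted over the list alone, with a list median of −0.28 (camera adjusted p = 3.89e-05; adjusted p = 0.476 with an estimated correlation; fry adjusted p = 0.122). Of 13 neuron markers 3 rose, such as egl-21 (0.81), of 10 intestine markers 3 rose and 2 fell, such as pept-1 (−2.34), of 15 germline mitosis and meiosis markers 1 rose, gld-1 (0.37), and of 142 cuticle collagen genes 6 rose and 5 fell, such as col-149 (−1.99). None of 15 moulting genes and none of 13 body wall muscle markers passed. Camera did not call the lists of neuron, intestine, germline, collagen, moulting or muscle genes. The list median, mean and camera direction differed in sign for zinc, iron and heme handling and for cytosolic heat shock proteins.

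In all, 2693 of 22548 probe sets changed with Cd in wild type, 1453 higher and 1240 lower, of which 625 changed at least 2-fold. The 3 arrays of one group lay wholly above the other's at 25% of probe sets, against 10% by chance. The direction of the majority turned with quantile normalization, 1264 higher and 1302 lower. It also turned with the 3′ minus 5′ signal as a covariate, where the limma count was 1770, 848 higher and 922 lower. Camera called 9 of 29 lists, of which none held with an estimated correlation, while fry (limma) called 8 of these 9 in the same direction.

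**Figure D3:**
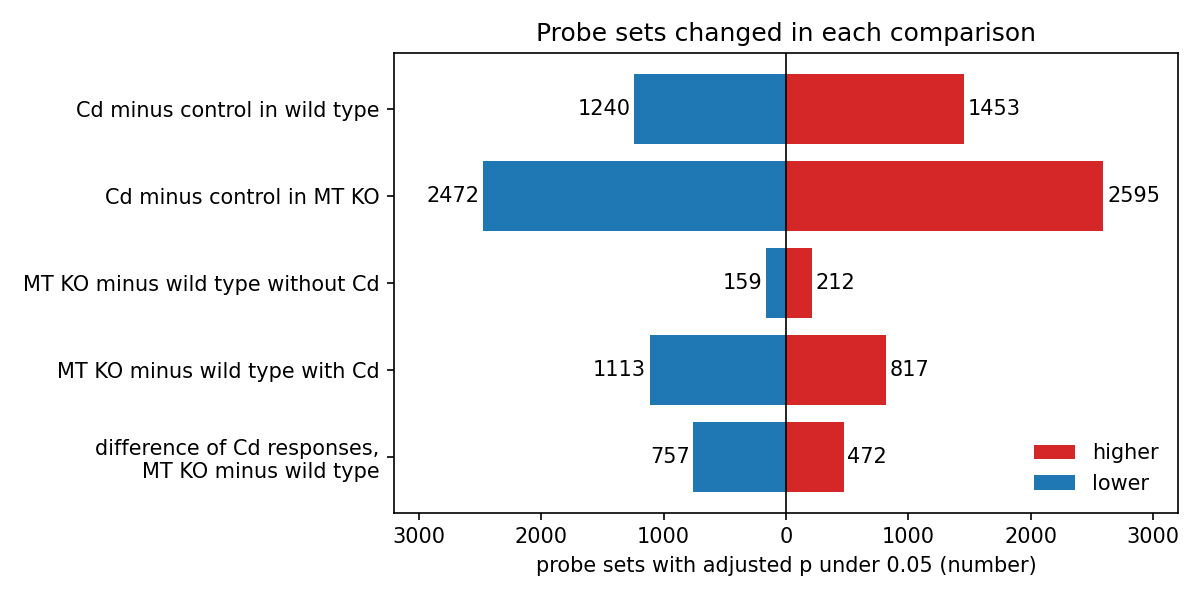
Number of probe sets with a limma adjusted p under 0.05 in each of the 5 comparisons. Bars to the right count higher and bars to the left lower probe sets, with 2595 higher and 2472 lower in MT KO with Cd against without Cd.

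In MT KO, Cd raised R08F11.4 most (log2 difference 6.99, SE 0.15, n = 3 per group, limma adjusted p = 3.33e-08), or 127-fold against a mean of 3.51, in the range of background. It also raised Y39G8B.7 (5.21, SE 0.25), F44E7.5 (4.33, SE 0.18), F56C3.9 (4.25, SE 0.23) and F15B9.6 (4.09, SE 0.17), all of which had risen in wild type. The remaining 5 were the zinc transporter gene zipt-2.3 (3.76), gst-38 (3.57), the insulin-like peptide gene ins-35 (3.49), B0348.2 (3.37) and C08E8.4 (3.21). The gene cdr-1 rose by 2.27 (SE 0.15), from 7.83 ± 0.06 to 10.10 ± 0.17 (SD, n = 3). For mtl-1 the difference was 0.44 (SE 0.21, limma adjusted p = 0.190), and for the 3 probe sets of mtl-2 it was 0.12, −0.30 and −0.02. The gene pcs-1 rose by 0.57 (SE 0.13, limma adjusted p = 0.0113) and hmt-1 fell by 0.51 (SE 0.13, limma adjusted p = 0.0176). The call of hmt-1 was lost without MT KO without Cd replicate 3 (limma adjusted p = 0.0578) and without MT KO with Cd replicates 2 or 3 (0.0542 and 0.0536).

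The gene nep-22 again fell most, by 4.70 (SE 0.11, n = 3 per group), and argk-1 fell by 3.65 (SE 0.23). Major sperm protein genes and relatives were among the other largest falls. These were msp-49 (−3.98, SE 0.25), msp-45 (−3.67, SE 0.25), msp-50 (−3.66, SE 0.20) and msd-2 (−3.73, SE 0.29), with F27C1.1 (−3.91), nsph-3.2 (−3.84), msrp-6 (−3.80) and msrp-5 (−3.66). The 10 largest falls had limma adjusted p between 3.33e-08 and 5.61e-05.

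Of 72 sperm markers 56 fell and none rose, with a list median of −2.32; gsp-4 (−2.44), msp-76 (−2.91) and msp-38 (−3.12) were among them. Adjusted over the list alone 57 fell, and camera called the list lower (adjusted p = 2.63e-33; adjusted p = 0.0612 with an estimated correlation). Of 15 germline mitosis and meiosis markers 5 fell, such as pgl-1 (−0.42) and glh-4 (−0.43; camera adjusted p = 0.00419; adjusted p = 0.0772 with an estimated correlation). Of 15 moulting genes 8 fell and 2 rose, with mlt-11 at −1.34, noah-2 at −1.26 and mlt-7 at 1.32 (camera adjusted p = 0.00419; adjusted p = 0.0607 with an estimated correlation). Of 10 pharynx markers 8 rose, such as marg-1 (1.81), myo-5 (1.71) and pha-4 (1.42), and of 13 neuron markers 9 rose, such as egl-21 (1.26), egl-3 (1.25) and unc-10 (0.81). Both lists were called higher by camera and held with an estimated correlation (adjusted p = 0.0444 and 0.0163 with an estimated correlation). Of 5 vitellogenin genes 3 fell, such as vit-1 (−2.32; camera adjusted p = 0.0115; adjusted p = 0.117 with an estimated correlation). Of the oocyte and embryo markers 1 of 17 rose, of the body wall muscle markers 2 of 13 rose, of the intestine markers 1 of 10 rose and 3 fell, and of the cuticle collagens 15 of 142 rose and 15 fell; camera called none of these 4 lists.

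Of 56 genes of fatty acid activation and beta-oxidation 28 fell and 3 rose, with acdh-8 at −2.65, acs-10 at −1.90 and ech-6 at −1.39, and adjusted over the list alone 30 fell and 5 rose. Of 16 genes of the methionine cycle and transsulfuration 9 fell and 1 rose, with cth-1 at −3.2, mtrr-1 at −2.17 and metr-1 at −1.80. Of 33 proteasome subunit genes 15 fell and none rose, with rpn-6.2 at −1.07 and pbs-3 at −0.47, and of 17 ER stress genes 9 fell and 1 rose, with pdi-2 at −0.74 and hsp-4 at −0.60. These 4 lists were called lower by camera and held with an estimated correlation (adjusted p = 0.0163, 0.0444, 0.0163 and 0.0244 with an estimated correlation, in that order). Of 18 fatty acid desaturase and elongase genes 6 fell and 1 rose, with fat-7 at −2.88 (camera adjusted p = 0.00419; adjusted p = 0.146 with an estimated correlation). Of 41 genes of glycolysis and the TCA cycle 8 rose and 5 fell, and the list was not called.

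Among genes of metal handling and defence, 4 of 6 cdr and numr genes rose, with cdr-4 at 1.67 (camera adjusted p = 0.00336; adjusted p = 0.0605 with an estimated correlation). Of 36 genes of zinc, iron and heme handling 6 rose and 11 fell, with ftn-1 at 3.17 and hrg-7 at −1.57 (camera adjusted p = 0.0115; adjusted p = 0.164 with an estimated correlation). Of 45 glutathione S-transferase genes 12 rose and 6 fell, with gst-24 at 2.80 (camera adjusted p = 0.0203; adjusted p = 0.111 with an estimated correlation). The call of that list was lost without MT KO without Cd replicate 1 (adjusted p = 0.0669) and with the 3′ minus 5′ covariate (adjusted p = 0.0898). Of 62 lysozyme and antimicrobial peptide genes 25 rose and 8 fell, with lys-7 at 1.97 and spp-18 at 1.83 (camera adjusted p = 0.00356; adjusted p = 0.0783 with an estimated correlation). Of 220 C-type lectin genes 24 rose and 22 fell, and clec-67 rose by 2.77. The other lists were not called, and median, mean and camera direction differed in sign for 7 of them: phytochelatin synthesis and metal efflux, antioxidant enzymes, UDP-glucuronosyltransferases, ABC transporters, cuticle collagens, intestine markers, and glycolysis and the TCA cycle.

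In all, 5067 of 22548 probe sets changed with Cd in MT KO, 2595 higher and 2472 lower, of which 1654 changed at least 2-fold. The arrays of the groups lay wholly apart at 43.2% of probe sets, against 10% by chance. With each array centred on its median, 3786 were higher and 2239 lower. The majority was lower with the 3′ minus 5′ covariate (2412 higher, 2415 lower) and among changes of at least 2-fold (678 higher, 976 lower). It was lower as well without MT KO without Cd replicates 2 (1968 higher, 2044 lower) or 3 (2041 higher, 2126 lower) and without MT KO with Cd replicate 3 (2260 higher, 2338 lower). Camera called 15 of 29 lists, and 6 held with an estimated correlation, while fry (limma) called all 15 in the same direction.

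Many of the same genes changed in both strains. Of the 2693 and 5067 probe sets, 941 were higher in both (167.2 would be shared by independent draws) and 739 were lower in both (135.9 by independent draws). Across all probe sets the log2 responses correlated at Pearson's r = 0.637 and Spearman's rho = 0.560; probe sets are not independent replicates. Of the 6050 probe sets changed in at least 1 strain, 86.1% had the same sign in both, and 30 were called in opposite directions.

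**Figure D4:**
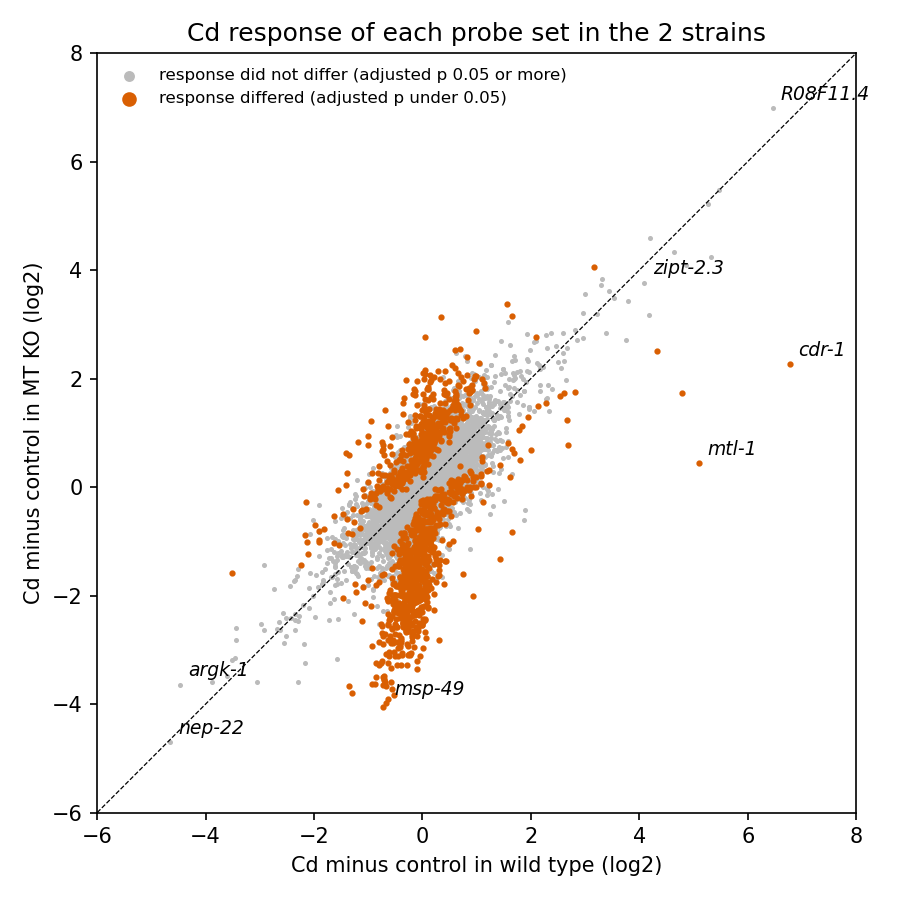
Cd response of each of 22548 probe sets in wild type (horizontal axis, log2) and in MT KO (vertical axis, log2). Orange points are the 1229 probe sets whose responses differed between the strains; R08F11.4 and nep-22 lie near the dashed line of equal responses, cdr-1, mtl-1 and msp-49 below it.

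Without Cd, mtl-2 differed most between the strains. The 3 probe sets of mtl-2 were lower in MT KO by log2 differences of −7.81, −7.60 and −4.80 (SE 0.15, 0.22 and 0.35, n = 3 per group, limma adjusted p between 1.72e-08 and 0.000359). The mtl-1 signal, itself near the median of all values in wild type, was lower by −1.18 (SE 0.21, limma adjusted p = 0.0291). That call was lost without wild type without Cd replicates 1 or 3 (limma adjusted p = 0.0655 and 0.0528) and without MT KO without Cd replicates 2 or 3 (0.0980 and 0.0785). It was also lost with the 3′ minus 5′ covariate (0.106), in a fit of only these 6 arrays (0.104) and with a floor under low values (0.0514). The gene cdr-1 was 17.1-fold higher in MT KO (log2 difference 4.1, SE 0.15, limma adjusted p = 2.43e-06), at 7.83 ± 0.06 against 3.73 ± 0.31 (SD, n = 3), so this fold too rests on a value in the range of background. The genes pcs-1 (0.42, limma adjusted p = 0.166) and hmt-1 (−0.08, limma adjusted p = 0.978) did not pass.

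Further genes higher in MT KO without Cd were the predicted chemoreceptor gene srw-85 (log2 difference 2.78, SE 0.18), T08G5.1 (2.48, SE 0.22), fat-7 (2.04, SE 0.17), the small heat shock protein gene hsp-12.3 (1.52, SE 0.20) and the acyl-CoA synthetase gene acs-2 (1.52, SE 0.26). The last 4 were sss-1 (1.41), C34D4.3 (1.33), ftn-1 (1.27) and cdf-2 (1.2), a gene for a zinc transporter of the cation diffusion facilitator family. Lower in MT KO were clec-67 (−2.24, SE 0.12), B0024.4 (−1.92), Y48E1B.8 (−1.91), the acyl-CoA oxidase gene acox-1.2 (−1.81), the infection response gene irg-1 (−1.73), B0348.2 (−1.69), the P-glycoprotein gene pgp-5 (−1.67), C34H4.1 (−1.65) and srlf-34 (−1.59). Their limma adjusted p lay between 3.69e-05 and 0.0261. Without MT KO without Cd replicate 2, the calls of acs-2, C34D4.3, ftn-1 and pgp-5 were lost (limma adjusted p = 0.0836, 0.0861, 0.0615 and 0.0505). Those of acs-2 and C34D4.3 were also lost without wild type without Cd replicate 2 (0.0658 and 0.0787) or 3 (0.0536 and 0.0580). Either was lost once more without another array: acs-2 without MT KO without Cd replicate 1 (0.0536), and C34D4.3 without wild type without Cd replicate 1 (0.0563) or MT KO without Cd replicate 3 (0.0528). That of C34D4.3 was lost with the 3′ minus 5′ covariate as well (0.0677). In a fit of only these 6 arrays, 14 of the 20 genes with the largest differences lost their call (limma adjusted p between 0.0533 and 0.144); mtl-2, cdr-1, srw-85, T08G5.1, clec-67 and srlf-34 did not.

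Camera called 3 of 29 lists in this comparison, and none held with an estimated correlation. Of 72 sperm markers 4 were higher in MT KO and none lower, with a list median of 0.56 and spe-55 at 0.95; adjusted over the list alone 32 were higher and 1 lower (camera adjusted p = 2.22e-18; adjusted p = 0.400 with an estimated correlation; fry adjusted p = 0.0769). The call of spe-55 was lost in a fit of only these 6 arrays (limma adjusted p = 0.0928). The genes of glycolysis and the TCA cycle (median 0.14, camera adjusted p = 0.000287) and those of the methionine cycle and transsulfuration (median 0.14, camera adjusted p = 0.0391) were called higher without any single member past the threshold over all probe sets. Adjusted over the list alone, 5 of 16 methionine cycle genes were higher and none of 41 genes of glycolysis and the TCA cycle. Each list had an adjusted p = 0.400 with an estimated correlation, and fry (limma) called neither (adjusted p = 0.055 for glycolysis and 0.0769 for the methionine cycle). Without wild type without Cd replicate 1, the array with the largest 3′ minus 5′ signal, both calls were lost (adjusted p = 0.0580 for each). With the 3′ minus 5′ covariate they were lost as well (adjusted p = 0.139 and 0.108). The call of the methionine list was further lost without wild type without Cd replicate 3 (0.0525), MT KO without Cd replicates 1 and 2 (0.118 and 0.0995) and with quantile normalization (0.0710). Of the remaining lists, C-type lectins held 4 higher and 2 lower genes of 220, glutathione S-transferases 3 lower of 45, such as gst-38 (−0.97; limma adjusted p = 0.089 in a fit of only these 6 arrays), and lysozymes and antimicrobial peptides 3 higher and 5 lower of 62. Pharynx, neuron and germline markers held no called gene. Median, mean and camera direction differed in sign for the cdr and numr genes, for zinc, iron and heme handling, for ABC transporters and for pharynx markers.

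In all, 371 of 22548 probe sets differed between the strains without Cd, 212 higher and 159 lower in MT KO, of which 70 differed at least 2-fold; the arrays lay wholly apart at 15.9% of probe sets, against 10% by chance. The count depended on single arrays: it was 168 without wild type without Cd replicate 2 (78 higher, 90 lower) and 170 without MT KO without Cd replicate 2. It was 23 in a limma fit of only these 6 arrays (9 higher, 14 lower) and 593 with array weights. With each array centred on its median, 202 were higher and 228 lower.

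With Cd, the strains differed at both metallothionein genes. The mtl-1 signal was lower in MT KO by a log2 difference of −5.84 (SE 0.21, n = 3 per group, limma adjusted p = 2.15e-06), and the 3 probe sets of mtl-2 by −7.81, −7.51 and −4.40. The gene cdr-1 no longer differed past the threshold (−0.42, SE 0.15, limma adjusted p = 0.149), nor did pcs-1 (0.44, limma adjusted p = 0.0758) or hmt-1 (0.14, limma adjusted p = 0.657). Higher in MT KO were srw-85 (3.61, SE 0.18), idpp-12 (2.41, SE 0.22), F20B10.3 (2.24, SE 0.30), W08E12.2 (2.22, SE 0.27), nspb-12 (2.02), srr-6 (2.01), abu-15 (1.97), T25E4.1 (1.96), piit-1 (1.95) and idpp-9 (1.94). Lower were rol-1 (−2.91, SE 0.39), a gene required for normal cuticle structure, E01G4.6 (−2.84, SE 0.46), T16A9.5 (−2.75, SE 0.26), the collagen genes col-49 (−2.57) and col-71 (−2.50), the hedgehog-like gene wrt-6 (−2.54), F27C1.1 (−2.43) and dao-4 (−2.40). Their limma adjusted p lay between 1.91e-05 and 0.0191. The calls of srr-6 and T25E4.1 were lost without wild type with Cd replicate 1 (limma adjusted p = 0.0678 and 0.0776) or MT KO with Cd replicate 3 (0.0507 and 0.0552), and that of T25E4.1 also without wild type with Cd replicate 2 (0.0621) or MT KO with Cd replicate 1 (0.0584).

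Camera called the lists of sperm, oocyte and germline markers lower in MT KO with Cd. Of 72 sperm markers 46 were lower and none higher, with a list median of −1.46; gsp-4 differed by −1.68, msp-76 by −1.91 and msp-38 by −1.97. Adjusted over the list alone 49 were lower (camera adjusted p = 1.65e-31; adjusted p = 0.0891 with an estimated correlation). Of 17 oocyte and embryo markers 7 were lower, such as cbd-1 (−0.60) and egg-1 (−0.63; camera adjusted p = 1.46e-05; adjusted p = 0.0555 with an estimated correlation). Of 15 germline mitosis and meiosis markers 5 were lower, such as gld-1 (−0.57) and glh-4 (−0.50), and adjusted over the list alone 7 were (camera adjusted p = 1.52e-06; adjusted p = 0.0293 with an estimated correlation).

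Genes of the moult and of somatic tissues moved in both directions. Of 15 moulting genes 7 were lower and 1 higher, with mlt-11 at −1.06, noah-2 at −1.02 and qua-1 at −1.34, and 10 were lower and 2 higher when adjusted over the list alone (camera adjusted p = 2.32e-05; adjusted p = 0.0293 with an estimated correlation). Of 142 cuticle collagen genes 20 were lower and 10 higher, such as dpy-3 (−1.40), dpy-2 (−1.22) and dpy-7 (−1.07); the list was not called. Of 13 neuron markers 6 were higher, such as unc-119 (0.52; camera adjusted p = 0.000363; adjusted p = 0.0293 with an estimated correlation). Of 10 pharynx markers 5 were higher, such as marg-1 (1.05), pha-4 (0.89) and tnt-4 (0.72; camera adjusted p = 1.53e-06; adjusted p = 0.0664 with an estimated correlation). No body wall muscle or intestine marker differed. Of 33 proteasome subunit genes 2 were lower, with rpn-6.2 at −0.85 (camera adjusted p = 0.000896; adjusted p = 0.0664 with an estimated correlation). Of 56 genes of fatty acid activation and beta-oxidation 9 were lower and 2 higher, with acdh-8 at −1.77 and acs-10 at −1.52, and fat-7 was higher by 1.72; their lists were not called. Median, mean and camera direction differed in sign for 7 lists: cytochrome P450s, ABC transporters, C-type lectins, cuticle collagens, fatty acid desaturases and elongases, the methionine cycle, and ribosomal proteins.

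In all, 1930 of 22548 probe sets differed between the strains with Cd, 817 higher and 1113 lower in MT KO, of which 668 differed at least 2-fold. The arrays lay wholly apart at 25.9% of probe sets, against 10% by chance. With each array centred on its median, 1131 were higher and 1059 lower. The limma count was 1155 without wild type with Cd replicate 1. Camera called 7 of 29 lists, and 3 held with an estimated correlation, while fry (limma) called all 7 in the same direction.

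**Figure D5:**
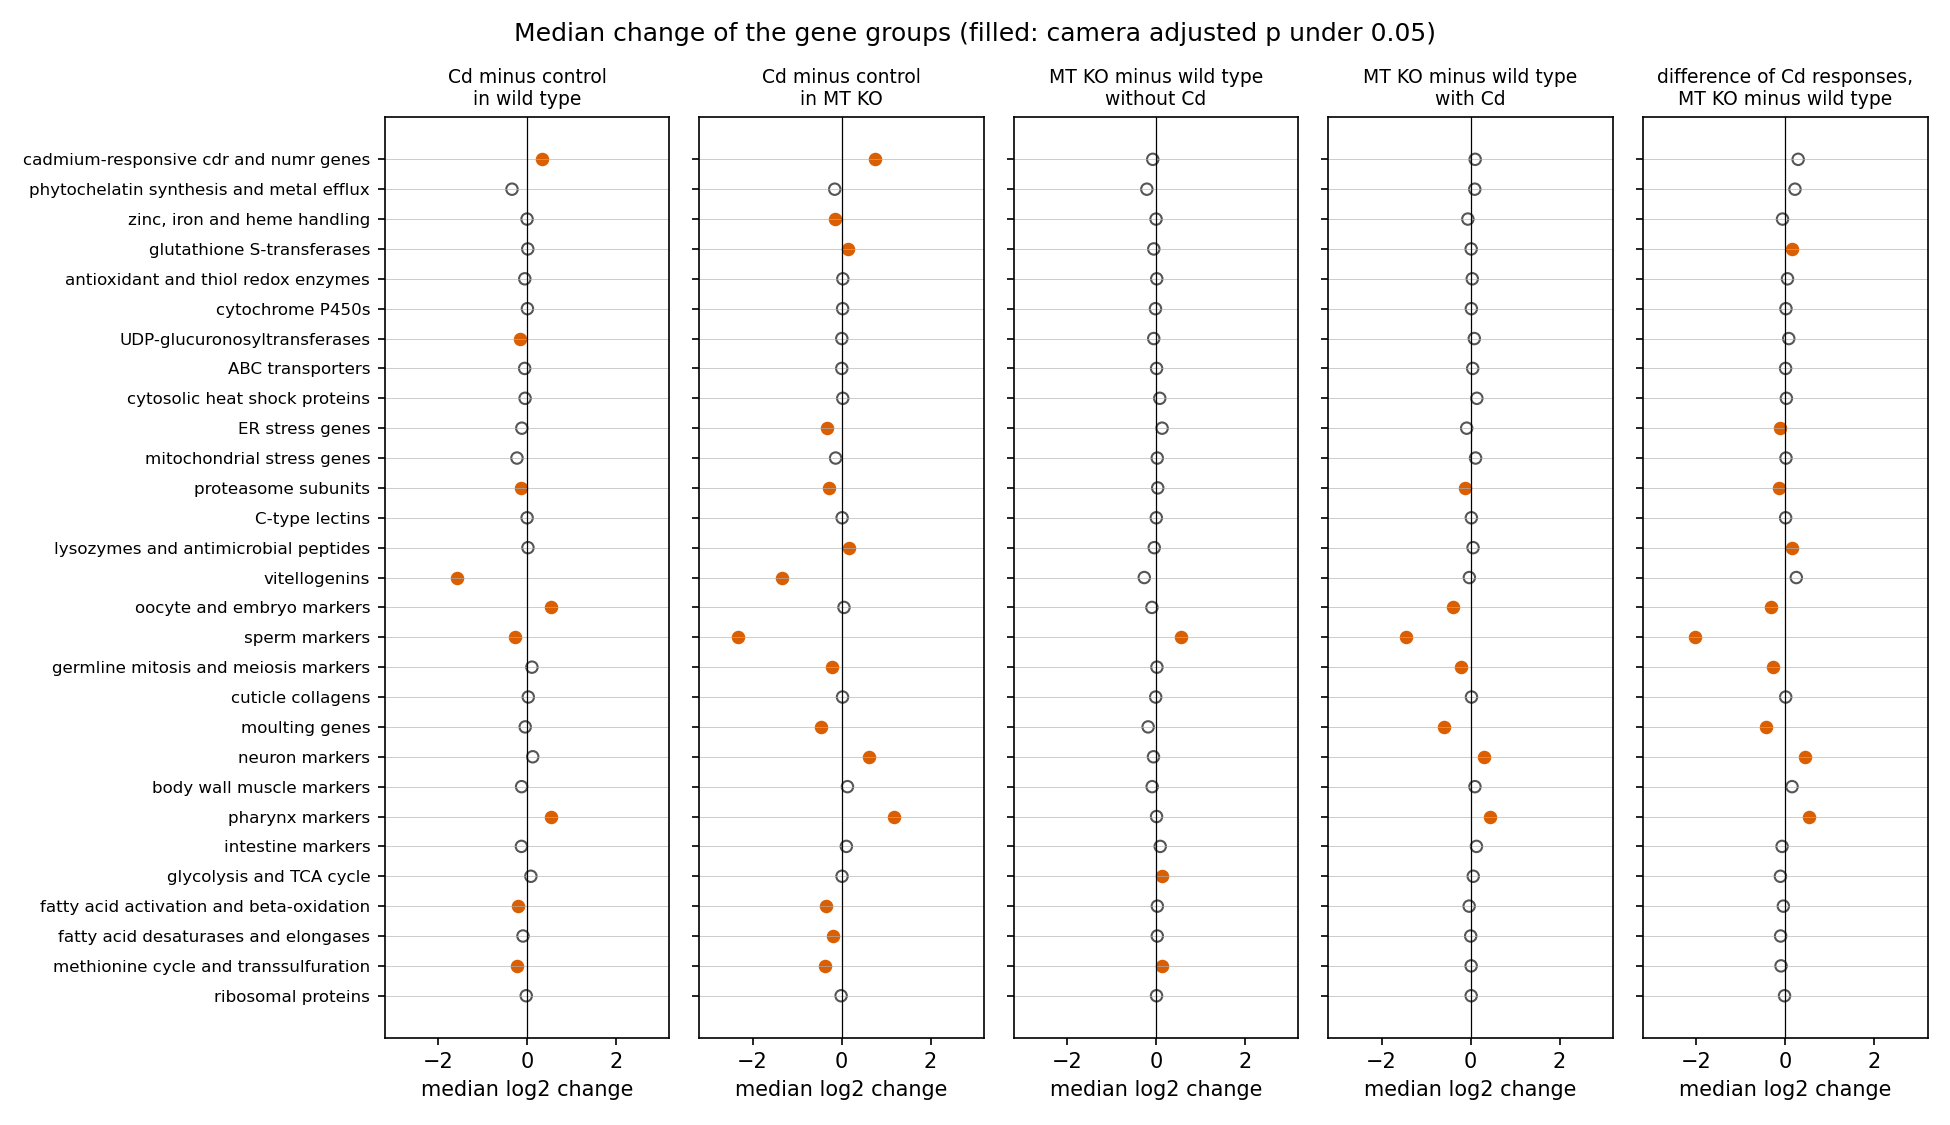
Median log2 change of the members of each gene list (rows) in the 5 comparisons (panels). Filled points mark lists called by camera at the preset correlation; the sperm markers had a median of −2.32 in MT KO with Cd against without Cd.

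The difference of the Cd responses was tested directly as the interaction of strain and Cd. It is the strain difference with Cd minus that without Cd, so a strain difference without Cd enters it with the opposite sign. Among genes whose response was lower in MT KO, mtl-1 (−4.66, SE 0.30, n = 3 per group, limma adjusted p = 0.000162) and cdr-1 (−4.51, SE 0.21, limma adjusted p = 7.36e-05) led. They were followed by nsph-3.2 (−3.32, SE 0.41), msp-49 (−3.31, SE 0.35), F27C1.1 (−3.27), msd-2 (−3.17), C15C6.2 (−3.12), C06A8.6 (−3.07), T08G5.1 (−3.06) and F53B6.4 (−3.0). Since MT KO lacks mtl-1, the difference of response of that gene was set by the genotype. For the 3 probe sets of mtl-2 the difference was 0.30, −0.21 and 0.40, with limma adjusted p of 0.571, 0.821 and 0.778. For pcs-1 it was 0.02 (limma adjusted p = 0.969) and for hmt-1 0.22 (limma adjusted p = 0.647).

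The response was higher in MT KO for clec-67 (2.73, SE 0.17), which read 7.78, 7.82, 5.54 and 8.31 in wild type without and with Cd and in MT KO without and with Cd. The others were idpp-12 (2.27, SE 0.31), B0024.4 (2.18), W08E12.2 (2.12), piit-1 (2.08), abu-8 (2.05), dod-22 (2.04), nspb-10 (2.03), dbd-20 (1.98) and chtb-3 (1.97). Their limma adjusted p lay between 0.000162 and 0.0328, and the call of dbd-20 was lost on leaving out any of 10 arrays, with limma adjusted p between 0.0557 and 0.0849, with a floor under low values (0.0553) and with the replicate number as a block (0.0538).

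Of 72 sperm markers, 47 had a lower response in MT KO and none a higher one, with a list median of −2.02; gsp-4 differed by −2.49 and gsp-3 by −2.44, and adjusted over the list alone 51 were lower and 1 higher (camera adjusted p = 2.3e-40; adjusted p = 0.0883 with an estimated correlation). Also called lower by camera were the germline mitosis and meiosis markers (4 of 15 lower, such as gld-1 at −0.59; adjusted p = 0.0637 with an estimated correlation) and the oocyte and embryo markers (2 of 17 lower; adjusted p = 0.164 with an estimated correlation). So were the moulting genes (2 of 15 lower and 1 higher, with mlt-11 at −0.96; adjusted p = 0.0883 with an estimated correlation) and the proteasome subunits (2 of 33 lower, with rpn-7 at −0.47; adjusted p = 0.0883 with an estimated correlation). Called higher were the pharynx markers (5 of 10 higher, with pha-4 at 0.92; adjusted p = 0.109 with an estimated correlation) and the neuron markers (3 of 13 higher, with unc-10 at 0.60; adjusted p = 0.0627 with an estimated correlation). The lysozymes and antimicrobial peptides were also called higher (5 of 62 higher and 2 lower, with spp-18 at 0.68; adjusted p = 0.164 with an estimated correlation). The calls of the ER stress genes (lower, camera adjusted p = 0.0372; adjusted p = 0.109 with an estimated correlation) and of the glutathione S-transferases (higher, camera adjusted p = 0.0474; adjusted p = 0.168 with an estimated correlation) were lost with quantile normalization (0.131 and 0.0518). On leaving out single arrays, 5 ended the call of the ER stress genes (adjusted p between 0.0563 and 0.0721) and 7 that of the glutathione S-transferases (0.0539 to 0.194). Median, mean and camera direction differed in sign for the cdr and numr genes, mitochondrial stress genes, C-type lectins and cuticle collagens.

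In all, 1229 of 22548 probe sets had a response that differed between the strains, 472 with a higher and 757 with a lower response in MT KO. Of the probe sets called in both strains, in the same or in opposite directions, 189 (11.1%) had a response that differed between the strains. With each array centred on its median, 717 were higher and 703 lower, and with array weights the limma count was 1869. Camera called 10 of 29 lists, of which none held with an estimated correlation, while fry (limma) called all 10 in the same direction.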

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

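The tests of a lower share of germline in the RNA, of Cd exposure or a swapped label, of the high-zinc response, of RNA integrity, of the splits with strain and Cd effects removed and of the neighbours of the metallothionein genes were chosen after the results they bear on had been seen.

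The Cd response differed between MT KO and wild type at 1229 probe sets by limma's test of the difference itself. In 1 of 100 splits of the 12 arrays, the real one, as many probe sets were called, and the highest of the others called 111; these splits mix strains and Cd within groups, which widens the spread, so they decide nothing. With the additive effects of strain and Cd removed first, 2 of 100 splits called as many, the real one and a split that called 1999. That split sets the same 6 arrays against the other 6 as the real one, and the highest of the remaining splits called 37. The interaction itself stays in these values and widens the spread in splits that mix it, so this test does not exclude chance as the source of the count. Whether the arrays came from separate cultures is not known either. For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. There the real split, 1 of 10 in each case, called 2693 probe sets for Cd in wild type (highest other 1), 5067 for Cd in MT KO (highest other 0), 371 for the strains without Cd (highest other 3) and 1930 with Cd (highest other 1).

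Genes named in the report are given here where the limma adjusted p of this difference, MT KO minus wild type on the log2 scale (n = 3 arrays per group), was under 0.05. Responses were lower in MT KO for mtl-1 (−4.66), cdr-1 (−4.51), T08G5.1 (−3.06), cdf-2 (−1.79), gst-33 (−1.01), hsp-12.3 (−1.36), hsp-4 (−0.61), clec-60 (−1.82), ilys-2 (−0.85), acdh-8 (−2.56), acs-10 (−2.01), rpn-6.2 (−0.99) and rpn-7 (−0.47). Among sperm genes and genes falling with them they were lower for msp-38 (−2.67), msp-45 (−2.99), msp-49 (−3.31), msp-50 (−2.92), msp-76 (−2.49), msrp-5 (−2.31), msrp-6 (−2.50), msd-2 (−3.17), nsph-3.2 (−3.32), gsp-3 (−2.44), gsp-4 (−2.49), spe-55 (−1.49) and sss-1 (−1.84). Among germline, oocyte and cuticle genes they were lower for gld-1 (−0.59), glh-4 (−0.46), egg-1 (−0.71), cpg-1 (−1.0), mlt-11 (−0.96), noah-2 (−1.14), dpy-2 (−1.03), dpy-3 (−1.04), dpy-7 (−1.05) and rol-1 (−2.48). The same direction held for F27C1.1 (−3.27), C15C6.2 (−3.12), C06A8.6 (−3.07), F53B6.4 (−3.0), T16A9.5 (−2.86), E01G4.6 (−2.76) and C34D4.3 (−2.16). The value of mtl-1, a gene that MT KO lacks, was set by the genotype.

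Responses were higher in MT KO for clec-67 (2.73), idpp-12 (2.27), idpp-9 (1.74), B0024.4 (2.18), W08E12.2 (2.12), piit-1 (2.08), abu-8 (2.05), abu-15 (1.80), dod-22 (2.04), nspb-10 (2.03), nspb-12 (1.91), dbd-20 (1.98), chtb-3 (1.97), F20B10.3 (1.93), Y48E1B.8 (1.93), B0348.2 (1.80), C34H4.1 (1.57), irg-1 (1.49) and srlf-34 (1.45). They were also higher for the acyl-CoA oxidase genes acox-1.1 (0.80) and acox-1.2 (1.87), for ugt-31 (1.28), spp-18 (0.68) and mlt-7 (1.35), for the pharynx markers marg-1 (1.01), myo-5 (1.1), pha-4 (0.92) and tnt-4 (0.52), and for the neuron markers egl-3 (0.67), unc-10 (0.60) and unc-119 (0.49). Of the lists, camera called the difference lower in MT KO for sperm markers (adjusted p = 2.3e-40), germline mitosis and meiosis markers (5.58e-05), oocyte and embryo markers (0.0085), moulting genes (0.00513), proteasome subunits (0.00171) and ER stress genes (0.0372). It called the difference higher for pharynx markers (5.58e-05), neuron markers (0.000197), lysozymes and antimicrobial peptides (0.016) and glutathione S-transferases (0.0474). With an estimated correlation none of these 10 calls held.

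Alternatives for this difference were run only on genes named for this comparison. Genes listed above but named for other comparisons alone were not run, so whether their calls held is not known. Among those run, the calls of 10 depended on the processing. The number of alternatives that ended the call, with the limma adjusted p under them, was 14 for hsp-4 (0.0529 to 0.159) and unc-119 (0.055 to 0.123), 12 for glh-4 (0.0517 to 0.079) and dbd-20 (0.0538 to 0.0849), and 11 for cpg-1 (0.0551 to 0.0981). It was 7 for egg-1 (0.0549 to 0.0576), gst-33 (0.0652 to 0.0734), marg-1 (0.0522 to 0.0764) and mlt-7 (0.0548 to 0.0693), and 4 for hsp-12.3 (0.0529 to 0.0623). Of these alternatives, those that left out a single array numbered 9 for hsp-4, glh-4 and cpg-1, 10 for unc-119 and dbd-20, 7 for egg-1 and gst-33, 6 for marg-1 and mlt-7, and 4 for hsp-12.3.

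The first pattern weighed is the lower level of sperm markers in MT KO than in wild type with Cd. A lower share of germline in the RNA would by itself raise all somatic markers alike. Pharynx markers (mean difference 0.56, SD 0.30, n = 10 genes) and body wall muscle markers (0.11, SD 0.093, n = 13 genes) moved apart (permutation p = 2e-05). The permutation takes genes of the same arrays as independent, and a lower share beside a change of pharynx genes would give the same values. The test therefore argues at most against a lower share acting alone, and a lower share of germline stays open. Cross-hybridisation among near-identical probe sets stays open. The 30 sperm markers outside the msp family on probe sets of 1 transcript had a median of −0.152, nearer to no change than the whole list. That median lay within the bounds set beforehand for cross-hybridisation as the cause. Its 95% interval, −0.738 to −0.0116, reached past the bound set against it, so the test does not decide. Of the 30, 22 were negative and 10 called lower. Developmental delay of the MT KO animals with Cd cannot be told apart from other explanations either. The vitellogenins, which differed by a median of −0.028, moved in neither of the predicted directions. They fell with Cd in both strains, so their strain difference does not separate delay from the effect of Cd itself. The moulting genes, called lower in MT KO with Cd by camera, were not part of this test. An effect of Cd on sperm genes in animals without metallothioneins, the biological difference of the design, stays open as untested.

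The second pattern is the set of 371 strain differences without Cd. The share of called genes on chromosome V was 24.1%, against 25.3% of other genes (odds ratio 0.939, 95% interval 0.704 to 1.24). It argues at most against variation linked to the metallothionein loci as the source of most calls of the main fit. Sequence variants under the probes would lower signals, but 47.8% of the 69 called genes on that chromosome were lower in MT KO (95% interval 35.6 to 60.2). Both shares count all calls of the main fit, whereas a fit of only the groups compared called 23 probe sets. No share was taken among those 23, so linked variation as the source of such steadier differences stays open. Lower RNA integrity of the wild-type arrays without Cd cannot be told apart from strain, since 191 of 371 calls were made again in the same direction with the 3′ minus 5′ covariate, between the bounds set for either outcome. With the covariate 321 probe sets were called, and the log2 differences with and without it correlated at r = 0.883 across probe sets. Linked variation near the loci stays open, with 7 of 200 neighbouring genes called, 3.5% against 1.65% (Fisher's exact p = 0.052), as does the absence of metallothioneins, which was not tested.

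The third pattern is the high level of cdr-1 in MT KO without Cd. Cd exposure like that of the arrays with Cd, or a swapped label, is argued against by the other 50 genes most raised by Cd in wild type. Their median share of that response was 0.024 (quartiles −0.058 and 0.21), against 0.6 for cdr-1. Both differences share the wild-type arrays without Cd, in which cdr-1 lay below the median of all values. A median over 50 genes cannot show exposure to less Cd that raised only some of them, so such exposure stays open. T08G5.1, for example, was higher by 2.48 in MT KO without Cd and by 4.79 with Cd in wild type. Release of the high-zinc response stays open, since 1 of 4 genes tested was higher: cdf-2 (1.2, limma adjusted p = 0.00917), but not hizr-1 (0.87, 0.0594), ttm-1 (−0.01, 1) or zipt-2.3 (−0.32, 0.842). An effect of missing metallothioneins on free metal in the animals was not tested.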

How the results depend on the processing

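The 3′ minus 5′ covariate was the alternative chosen after the data had been seen. Probe sets changed by Cd in wild type numbered 1770 with it and 625 at 2-fold or more; by Cd in MT KO, 1654 at 2-fold or more. Strain differences without Cd numbered 23 in a fit of the 2 groups compared, 593 with array weights and 70 at 2-fold or more. Those with Cd numbered 668 at 2-fold or more. A fit of the 2 groups compared also uses fewer arrays elsewhere, yet it called 1915 probe sets for Cd in wild type and 4378 in MT KO. For the strains with Cd it called 1822. Why the count without Cd fell most was not tested. Differences of response numbered 1869 with array weights and 666 at 2-fold or more, and changes in both strains 390 at 2-fold or more. The correlation of the responses was 0.659 among the brighter probe sets, 0.586 with array weights, 0.596 with the covariate and 0.68 among probe sets changed in at least 1 strain. Leaving out 1 array gave 168 to 461 strain differences without Cd (168 without wild type without Cd replicate 2, 170 without MT KO without Cd replicate 2), 1155 to 2139 with Cd (1155 without wild type with Cd replicate 1), and correlations of 0.585 to 0.65. With the replicate number as a block the counts were 2716, 5101, 312, 1876 and 1127; of 18 pairs of arrays with the same number, 5 correlated above 0.1, so the numbers were not taken as pairs. Other than for stricter thresholds, the cause of these shifts was not tested.

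Of 6624 gene results under alternatives, 6353 kept direction and side of the threshold, 250 lost and 4 gained the call, and 17 changed sign, none of them called. For mtl-2 with Cd in wild type these were 0.0116 (array weights), 0.25 and 0.0743 (covariate), with a left-out range of −0.30 to 0.0515. For mtl-2 in MT KO they were 0.0438 (arrays centred on the median), 0.0594 (array weights) and 0.254 (covariate), with left-out ranges of −0.0483 to 0.207 and −0.318 to 0.348. Left-out ranges were −0.396 to 0.00829 for the difference of response of mtl-2, −0.109 to 0.136 for that of pcs-1, and −0.00305 to 0.309 for hmt-1 between strains with Cd; the cause was not tested. Signal over background limits mtl-1 and 2 of the 3 mtl-2 probe sets in MT KO and cdr-1 in wild type without Cd, whose group means lie below the median of all values, 4.03, although single MT KO arrays lie above it; the difference of response of cdr-1 (−4.51) rests on such a mean.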

Other observations

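The gene families of this part, and the tests on them, were chosen after the results had been seen, from 233 families formed by symbol prefix. Camera called the families flp and nlp, whose prefixes are used for neuropeptide genes, higher with Cd in both strains, at the preset correlation alone. Some genes of the list of lysozymes and antimicrobial peptides also bear the nlp prefix, so nlp may not stand for neuropeptide genes alone. Of 25 flp genes 13 rose in wild type (median 0.515, camera adjusted p = 1.68e-07) and 20 in MT KO (median 0.998, adjusted p = 1.4e-10), and of 58 nlp genes 16 rose and 1 fell in wild type (median 0.256, adjusted p = 4.1e-06) and 40 rose in MT KO (median 0.675, adjusted p = 3.93e-12). None of these calls held with an estimated correlation (adjusted p = 0.383, 0.289, 0.323 and 0.264). The difference of the responses was called for flp (5 of 25 higher, adjusted p = 5.51e-06; 0.501 with an estimated correlation) and for nlp (7 of 58 higher, adjusted p = 3.56e-07; 0.459 with an estimated correlation).

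Of 34 mrpl genes, which encode mitochondrial ribosomal proteins, 16 fell with Cd in wild type (median −0.319, camera adjusted p = 1.87e-10) and 13 in MT KO (median −0.238, adjusted p = 6.44e-05), with adjusted p of 0.23 and 0.326 with an estimated correlation. All 23 msp genes measured fell with Cd in MT KO (median −2.9, camera adjusted p = 2.61e-26, 0.298 with an estimated correlation). Cross-hybridisation among near-identical sperm probe sets stays open, so these may not be 23 separate readings. Of 11 abu genes 7 rose with Cd in MT KO (median 1.78, camera adjusted p = 0.000904, 0.304 with an estimated correlation).

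Next to mtl-2, T08G5.1 was higher in MT KO without Cd (log2 difference 2.48, SE 0.22, limma adjusted p = 0.00121), and next to mtl-1, K11G9.5 was lower (−0.88, SE 0.15, limma adjusted p = 0.0234). Both genes were singled out after their values had been seen.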
